A study of Drosophila melanogaster with 7 samples.

How the data were processed

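Single-cell RNA libraries of the larval ventral cord were analysed from the deposited 10x Genomics matrices, 1 per library, for 5 unsorted controls and 2 GFP-sorted libraries. Per the labels' protocols, the cords were dissected into medium with blockers of neural activity (TTX at 0.1 µM, AP-5 at 50 µM, CNQX at 20 µM) and were dissociated for 1 h at 25 °C. Between 9000 and 10000 cells were loaded per library, per the labels. The values are UMI counts per gene and barcode, made by the authors with Cell Ranger on genome build BDGP6, per the file headers and the submitters' processing notes. Those notes also name Seurat version 3, and no step made with it is used here. The deposited counts are unfiltered: every barcode of the kit list is present, 737280 in controls 1, 3 and 4 and 6794880 in controls 2 and 5 and both sorted libraries. The labels give the same kit version for all libraries, while the barcode lists differ in length, so the list length was treated as a batch. The files list 17739 features, or 17808 in control 5 and the Proc-Gal4 sorted library, and 17688 genes shared by all were used. A feature named RFP_GFP is the reporter sequence.

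Cells were barcodes with at least 0.1 of the 99th percentile UMI count of the top 5000 barcodes of their library, at least 500 UMIs, at least 300 genes and under 15% mitochondrial UMIs. The resulting UMI minimum was 5584.3, 5039.3, 5698.9, 4316.8 and 5009.5 in controls 1 to 5, 1880.5 in the twit-Gal4 sorted library and 2194.5 in the Proc-Gal4 sorted library. Scrublet scores (scanpy 1.11.5) were computed per library. Scrublet's own threshold marked 1 to 7 cells per library and was not used. Instead the highest scores were removed at 0.8% per 1000 cells, which took 1.95% to 3.76% of cells.

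The controls were clustered together on log-normalised counts, as z-scores within each library, over 3000 variable genes. The 641 genes of the fixed gene lists and the mitochondrial genes were left out of this step. It used 50 principal components, 15 neighbours and Leiden clustering at resolution 2 (Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3, figures with matplotlib 3.10.9). Clusters were named by marker genes fixed before the data were examined, as were the gene lists, the tests of the comparisons and the alternatives, but not most tests of explanations. A name needed at least 3 markers up by 0.5 (log2, with a prior of 20 CPM) and a mean score of at least 0.5. Of 60 clusters, 16 stayed unnamed. After the clusters were seen, 2 clusters led by nw and ImpE2, genes of disc epithelium, were kept unnamed. So was 1 cluster of 203 cells with ribosomal precursor RNA among its leading genes, whose mean score for mature neurons was 0.63. The first pair held 1.33%, 0.131%, 21.4%, 0.863% and 0.205% of controls 1 to 5, and the other 0.645%, 2.46%, 0%, 0.500% and 2.60%. Of the 13 immature and 7 mature clusters, 1 each was led by more markers of another class, so these classes are not compared between sorted and unsorted libraries.

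Counts were summed per control and class, leaving out classes of under 10 cells in a library. They were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): TMM scaling, filterByExpr, a robust quasi-likelihood fit and test with the library as a block, and Benjamini-Hochberg adjustment with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F. CPM values beside tests use the TMM library sizes. Both classes of a comparison come from the same libraries, which gives the pairing. The deviations of the 2 class sums of a library from their class means correlated across genes at 0.872, 0.908, 0.732, 0.848 and 0.895 in controls 1 to 5 for mature and immature neurons, and at 0.819, 0.628, 0.691, 0.820 and 0.882 for motor and mature neurons. Each was above the correlation with any other library. Transmitter classes were mature neurons with at least 2 UMIs of 1 transmitter and at least 80% of all transmitter marker UMIs, and those marker genes were left out of the calls.

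The 19 gene lists (voltage-gated and potassium channels, transmitter receptors, monoamine receptors, neuropeptides, neuropeptide receptors, synaptic vesicle and active zone, dpr and DIP, beat and side, axon guidance and adhesion, BMP and activin signalling, Hox genes, lineage transcription factors, temporal and ecdysone response genes, axonal transport, ribosomal proteins, oxidative phosphorylation, glycolysis, cell cycle, and dissociation and heat stress) were tested with camera at a preset correlation of 0.01, and with an estimated correlation as an alternative. Genes named in the text are, per comparison, the 10 largest increases and decreases among called genes with the same direction in every library, at least 20 UMIs per library, no clustering or marker role and a symbol other than a CG or RNA number, and the 4 largest called changes of each list. For the sorted libraries they are twit, Proc, VGlut, eve and Dad, and the 10 largest and 10 smallest CPM ratios among genes with at least 50 UMIs that lie 2-fold over the highest control or under 0.5 of the lowest, whatever the symbol.

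The test was checked on simulated data with 50 changed genes per fold size, as many up as down, and 1 dispersion for all genes. Most simulated genes were unchanged (7136 of 7336 for mature against immature neurons), while 4766 genes were called there in the measured data. The shares of false calls therefore hold for the simulated setting and are not the error rate of the measured data. In the mature against immature comparison (7336 genes) it called 16% of genes changed 1.5-fold, 74% of those changed 2-fold and 94% of those changed 4-fold, and 4.7% of its calls were unchanged genes. For motor against mature neurons (6710 genes) the values were 22%, 90%, 100% and 1.9%, for cholinergic (6822 genes) 22%, 88%, 96% and 3.18%, for GABAergic (6844 genes) 22%, 76%, 100% and 3.9%, and for glutamatergic (6829 genes) 20%, 66%, 94% and 3.45%.

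Each sorted cell took the class most common among its 15 nearest cells of the control of its genotype. CPM ratios have 95% exact Poisson intervals and shares exact Clopper-Pearson intervals, which cover counting error only. The floor for genes at 0 is 3 counts. For shares of cells with a UMI, cells were also thinned to 1000 UMIs. No pair of libraries was a copy of another. Gene positions are from Ensembl release 115 (BDGP6.54), matched by gene identifier, while the deposited matrices name only BDGP6. The alternatives tried were DESeq2 1.42.0, no filter on low counts, no replicate block, leaving out each control, either barcode list alone, at least 1000 UMIs, doublets kept, Leiden resolutions 1 and 3, a transmitter gate of 1 UMI and 100%, an estimated camera correlation, classes from all 5 controls and the mean of per-cell CPM.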

Results

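Single-cell RNA was measured in the ventral cord of wandering fruit fly larvae, in 7 droplet libraries. The control group held 5 libraries of unsorted cells. Control 1 came from w1118, a common laboratory strain, control 2 from larvae with nuclear GFP driven by twit-Gal4, and control 3 from a futsch-GFP, vGlut-RFP line. Control 4 carried nuclear GFP driven by RN2-Gal4 and control 5 nuclear GFP driven by Proc-Gal4. The other 2 libraries held cells sorted for GFP, 1 from the genotype of control 2 and 1 from the genotype of control 5. Over all barcodes, controls 1 to 5 held 52025574, 54159655, 62562960, 59724615 and 58736553 UMIs (unique molecular identifiers, which count RNA molecules). The twit-Gal4 sorted library held 26050763 UMIs and the Proc-Gal4 sorted library 42534869. After filtering, controls 1 to 5 kept 2637, 3054, 2369, 4402 and 3417 cells, the twit-Gal4 sorted library 2522 and the Proc-Gal4 sorted library 4508. The median UMI count per cell lay between 7419 and 10146.5 in the controls, and was 4690.5 and 6329 in the twit-Gal4 and Proc-Gal4 sorted libraries. The median share of mitochondrial UMIs was 1.70% to 3.38% in the controls, 7.19% in the twit-Gal4 sorted library and 1.99% in the Proc-Gal4 sorted library. The 5 controls differ in genotype, so they came from different animals, and the spread between them mixes genotype with replicate. The p-values measure only the spread between these samples. The labels do not say whether a sorted library and the control of its genotype came from separate animals.

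The series is described as an atlas of the cord, and the composition of the unsorted libraries shows which cell classes it holds. Immature neurons were the largest named class, at 26.8% ± 15.2 of cells (mean ± SD, n = 5), followed by mature neurons outside the motor, monoaminergic and neurosecretory classes, at 18.8% ± 9.32. Neuroblasts and ganglion mother cells, the dividing progenitors, made up 7.40% ± 3.45 and motor neurons 3.68% ± 1.95. Glia, counted as astrocytes, cortex glia and surface glia together, made up 6.50% ± 1.84. Unnamed clusters of 152 and 36 cells had the glial marker wrapper among their leading genes and lie outside this share. Neurosecretory neurons made up 1.52% ± 0.360 and monoaminergic neurons 0.729% ± 0.232 (1.499% with doublets kept and 1.25% at Leiden resolution 1). Among glia, astrocytes made up 2.39% ± 0.728, cortex glia 2.06% ± 0.370 and surface glia 2.05% ± 1.01 of all cells. Clusters that no marker set named held 34.3% ± 16.4 of cells. No cluster was named muscle, trachea or fat body, which does not bound their share, since unnamed clusters remained. Control 3 stood apart: 1.52% of its cells were immature neurons against 23.6% to 37.6% in the other 4 controls, 3.04% were mature neurons against 19.7% to 27.9%, and 63.4% were unnamed. These shares depend on the UMI minimum, which was taken from the largest barcodes of each library. With at least 1000 UMIs in every library, immature neurons made up 32.7% ± 2.71, mature neurons 17.6% ± 2.54, motor neurons 1.92% ± 0.428, neurosecretory neurons 0.854% and glia 9.25% ± 1.83 of cells, with astrocytes at 3.69% and cortex glia at 3.81%. A cluster of 35 cells was named trachea there (0.135% ± 0.0708). Another, named muscle there (0.637% ± 0.228) and so outside the glia share, has the leading genes Swim, trol and Tsf1 of a cluster named surface glia at the UMI minimum of each library.

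**Figure D1:**
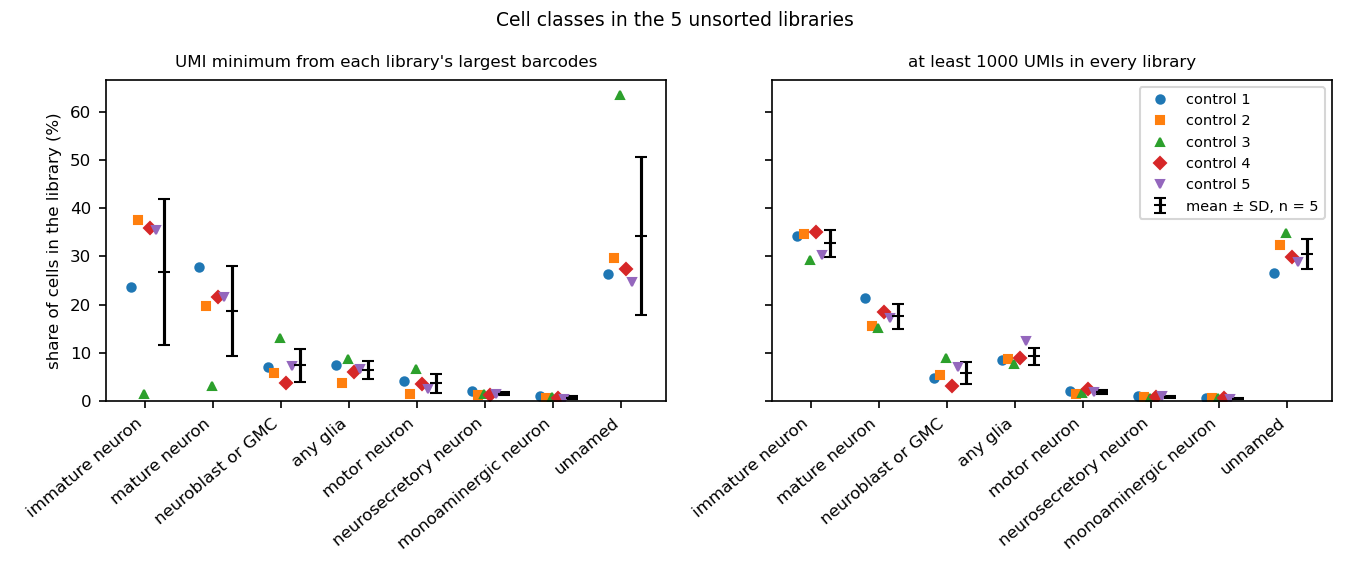
Share of cells per named class (vertical axis, percent of the cells of a library) in the 5 unsorted libraries, with 1 point per library and the mean ± SD, at the UMI minimum of each library (left) and at 1000 UMIs or more in every library (right). The immature share of control 3 is 1.52% on the left and 29.2% on the right.

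Among mature neurons outside the motor, monoaminergic and neurosecretory classes, markers of acetylcholine synthesis and loading gated 38.1% ± 9.28 as cholinergic (mean ± SD, n = 5), markers of GABA 33.3% ± 4.24 and VGlut 11.7% ± 3.82. After every cell was thinned to 1000 UMIs the cholinergic share was 8.92%, the GABAergic share 19.1% and the glutamatergic share 10.6%, so the order of the first pair depended on depth. With a gate of 1 UMI and 100% the glutamatergic share was 7.11%. With that gate the cholinergic share lay between 32.1% and 35.6% in all 5 controls, without the split by barcode list.

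The first comparison asked which genes separate mature from immature neurons of the same cord. Genes of sugar breakdown were higher in mature neurons together: all 12 tested glycolysis genes rose, with a median log2 fold change of 3.51. Ldh, which interconverts pyruvate and lactate, stood at 486 ± 177 CPM (counts scaled to a common library size, mean ± SD, n = 5) in mature and 14.8 ± 11.1 in immature neurons. The glycolytic enzyme gene Pglym78 stood at 1200 ± 289 and 42.5 ± 20.4 CPM, Ald1 (aldolase) rose by 4.42 ± 0.22 (log2 fold change ± SE) and PyK (pyruvate kinase) by 4.20 ± 0.21. Receptors for neuropeptides (29 of 31) and for monoamines (17 of 17) were higher in mature neurons as well. The largest decreases were RpS5b, a second gene for a ribosomal protein, at 2.96 ± 1.85 against 103 ± 72.8 CPM, and Eip93F, an ecdysone-induced transcription factor (-4.84 ± 0.31). RpS5b lies at 3R 14900432 to 14901563 and Pglym78 at 3R 29148248 to 29149901 (build BDGP6.54).

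The gene lists divided in the following way. Glycolysis genes had a camera adjusted p of 1.19e-12 upward (adjusted p = 0.274 with an estimated correlation). Neuropeptide receptors included SIFaR (7.32 ± 0.49), ETHR (5.30 ± 0.24) and AstA-R1 (5.05 ± 0.18), with 0 lower and 2 not called (adjusted p = 5.94e-15, and adjusted p = 0.274 with an estimated correlation). Monoamine receptors included Octbeta2R (6.62 ± 0.19), Octbeta1R (5.21 ± 0.20) and Dop2R (4.58 ± 0.30), which bind octopamine and dopamine (adjusted p = 9.33e-13, and adjusted p = 0.274 with an estimated correlation). Of 16 tested neuropeptide genes, 10 were higher, 1 lower and 5 not called, with spab at 322 ± 138 against 2.81 ± 1.86 CPM and Dh31 at 422 ± 250 against 4.01 ± 2.99 CPM (adjusted p = 0.000899, and adjusted p = 0.329 with an estimated correlation). Voltage-gated and potassium channel genes were higher in 23 of 24 cases and lower in 1, among them KCNQ (5.24 ± 0.23) and the calcium-activated channel slo (4.63 ± 0.29) (adjusted p = 1.46e-12, and adjusted p = 0.300 with an estimated correlation). Of 25 fast and metabotropic transmitter receptors 23 were higher, such as the GABA receptor Rdl (3.65 ± 0.13), 1 was lower and 1 not called (adjusted p = 9.82e-10, and adjusted p = 0.274 with an estimated correlation). Synaptic vesicle and active zone genes were higher in 25 of 30 cases, with Rbp (3.01 ± 0.16) and Fife (2.90 ± 0.18) (adjusted p = 2.19e-14, and adjusted p = 0.274 with an estimated correlation). The mature class was named by other synaptic genes, so this list is not independent of the naming. Genes of the other lists that vary together with those markers are not independent of it either, though no list gene served in the clustering.

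Surface proteins of the dpr and DIP families, which bind each other between neurons, were higher in 28 of 32 cases, such as DIP-iota (3.75 ± 0.38) and dpr5 (3.57 ± 0.24), with 4 not called (adjusted p = 4.17e-13, and adjusted p = 0.274 with an estimated correlation). All 21 tested beat and side genes were higher, with beat-VII at 3.81 ± 0.16 (adjusted p = 1.74e-12, and adjusted p = 0.274 with an estimated correlation). Nuclear oxidative phosphorylation genes moved less: 57 of 62 were higher, 1 lower and 4 not called, with a median of 0.64 and COX4 at 1.10 ± 0.10 (adjusted p = 1.74e-12, and adjusted p = 0.353 with an estimated correlation). The other lists were mixed, and camera called none of them. Temporal and ecdysone response genes had 7 higher, 5 lower and 4 not called, with the nuclear receptor gene Hr38 up by 6.16 ± 0.26 and the RNA-binding protein gene Syp at 263 ± 110 against 1358 ± 356 CPM. Of 58 lineage transcription factors 14 were higher, such as Kr (6.01 ± 0.36) and nub (4.63 ± 0.42), 24 lower, such as ap (-2.65 ± 0.29) and B-H1 (-2.40 ± 0.36), and 20 not called. Hox genes had 4 higher, with Abd-B (3.60 ± 0.25) and abd-A (3.54 ± 0.16), 1 lower and 2 not called. Axon guidance and adhesion genes had 10 higher, such as CadN2 and Dscam2 (2.62 ± 0.17), 19 lower, such as stan (-2.06 ± 0.14), and 14 not called. Axonal transport genes had 4 higher, among them futsch (3.38 ± 0.17), which codes for a microtubule-associated protein, 3 lower and 8 not called. BMP and activin signalling genes had 4 higher, 6 lower, such as brk (-1.61 ± 0.13), and 6 not called. Cell cycle genes had 2 higher, 8 lower, such as CycB3 (-1.89 ± 0.21), and 12 not called. Cytoplasmic ribosomal proteins had 6 higher, 20 lower, such as RpL38 (-0.69 ± 0.08), and 57 not called. Dissociation and heat stress genes had 4 higher, among them sr (5.09 ± 0.25), 6 lower, among them Hsp27 (-1.82 ± 0.13), and 6 not called.

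Overall counts came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which called 2186 genes higher and 2580 lower of 7386 tested in 5 pairs of class sums. Of these, 1317 and 2163 had not served as clustering features. Every gene valued in the preceding account had an adjusted p of 0.000515 (Syp) or less and the same direction in 5 of 5 libraries. Adjusted over the list alone, the counts were the same except for oxidative phosphorylation (59 higher), dpr and DIP (29 higher), BMP and activin (5 higher, 8 lower), cell cycle (1 higher, 7 lower), ribosomal proteins (4 higher, 9 lower) and Hox genes (4 higher, 2 lower). Without the library as a block, the counts were 1152 and 1050.

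The next comparison set motor neurons, the cells that drive the body wall muscles, against other mature neurons. Of the 3 motor clusters, 1 of 107 cells had Ilp7 and GstD2 but none of the motor markers among its leading genes. It gave 20 of the 46 motor cells of control 2. With doublets kept, a cluster with Ilp7, GstD2, Vmat and Tdc2 among its leading genes was named monoaminergic. Another motor cluster, of 141 cells, came from control 3 alone, which held 158 motor cells. The class may thus hold cells other than motor neurons. Motor neurons were higher for the adhesion gene Fas2, at 1755 ± 374 against 353 ± 56.1 CPM (mean ± SD, n = 5), and for cv-2, which codes for a BMP-binding protein, at 431 ± 137 against 52.4 ± 17.4 CPM. The genes kay and Jra, which code for the fly Fos and Jun transcription factors, and puc, a target of JNK signalling, were also higher: kay stood at 482 ± 243 against 73.5 ± 21.4 CPM, Jra at 226 ± 78.5 against 47.6 ± 13.4 and puc at 288 ± 151 against 96.0 ± 39.0. Of 49 lineage transcription factors 32 were lower, with acj6 at 1.39 ± 0.944 against 60.4 ± 21.7 CPM. Surface recognition genes were lower in the motor class too, 24 of 32 dpr and DIP genes and none higher, with DIP-lambda at 0.643 ± 0.911 against 55.7 ± 13.1 CPM. Fas2 lies at X 4132887 to 4206093, kay at 3R 29765995 to 29794113, acj6 at X 15350239 to 15379064 and DIP-lambda at 2R 326768 to 705848.

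Camera called 11 of the 19 lists in this comparison. The dpr and DIP genes had an adjusted p of 2.35e-12 downward (adjusted p = 0.343 with an estimated correlation). In the lineage transcription factor list, the 32 lower genes included slou (-6.33 ± 0.46), kn (-6.09 ± 0.38) and otp (-5.07 ± 0.38), while 7 were higher, with bi (2.75 ± 0.18), and 10 not called (adjusted p = 4.10e-11, and adjusted p = 0.105 with an estimated correlation). The beat and side genes had 13 lower, such as side-IV (-3.16 ± 0.25), 2 higher and 6 not called (adjusted p = 2.30e-06, and adjusted p = 0.343 with an estimated correlation). Axon guidance and adhesion genes had 29 lower, such as NetB (-3.41 ± 0.41) and robo2 (-2.67 ± 0.20), 3 higher, Fas2 among them, and 10 not called (adjusted p = 1.20e-05, and adjusted p = 0.383 with an estimated correlation). Transmitter receptors had 12 lower, such as mAChR-B (-3.03 ± 0.35) and GluRIA (-2.12 ± 0.19), none higher and 12 not called (adjusted p = 4.87e-05, and adjusted p = 0.470 with an estimated correlation). Neuropeptide genes had 6 lower, such as spab (-6.53 ± 0.39) and Dh44 (-3.77 ± 0.35), 1 higher and 8 not called (adjusted p = 8.91e-05, and adjusted p = 0.105 with an estimated correlation). The 1 higher neuropeptide gene was Ilp7 (5.31 ± 1.31, edgeR quasi-likelihood adjusted p = 0.0341), whose call ended without control 1, 2, 3 or 5. Monoamine receptors had 8 lower, such as Dop1R1 (-4.24 ± 0.32), 2 higher and 6 not called (adjusted p = 0.00333, and adjusted p = 0.414 with an estimated correlation). All 5 tested Hox genes were lower, led by pb (-5.11 ± 0.42) (adjusted p = 0.00593, and adjusted p = 0.343 with an estimated correlation), and this list call ended at Leiden resolution 3 (camera adjusted p = 0.122). The lower calls of Ubx, Antp and abd-A ended when single controls were left out.

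Upward calls were fewer. Axonal transport genes had 8 higher and 7 not called, with the kinesin gene Khc (1.38 ± 0.11) and Arl8 (1.09 ± 0.12) (adjusted p = 0.00251, and adjusted p = 0.343 with an estimated correlation), and this list call ended with the longer barcode list alone (camera adjusted p = 0.0545). Dissociation and heat stress genes had 7 higher, kay, Jra and puc among them, 2 lower and 5 not called (adjusted p = 0.00692, and adjusted p = 0.343 with an estimated correlation). The glutathione transferase gene GstD1 of this list stood at 1383 ± 445 against 34.7 ± 61.9 CPM (log2 fold change 6.99 ± 1.08, edgeR quasi-likelihood adjusted p = 0.00771), and 7.77 without control 3. Its call ended with the shorter barcode list alone. Oxidative phosphorylation genes had 11 higher and 49 not called (adjusted p = 0.0121, and adjusted p = 0.750 with an estimated correlation). That call ended without control 3 (camera adjusted p = 0.0549), without control 5 (0.0564) and at 1000 UMIs or more (0.0542). The lists that camera did not call were glycolysis (5 higher, 7 not called), neuropeptide receptors (4 higher, 7 lower), synaptic vesicle and active zone (4 higher, 11 lower), channels (3 higher, 10 lower), BMP and activin (5 higher, 4 lower), temporal genes (4 lower), cell cycle (2 lower) and ribosomal proteins (11 higher, 2 lower). In the BMP list cv-2 was up by 3.02 ± 0.18 and put, a receptor gene, down at -1.33 ± 0.16.

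Counts by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 1134 genes higher and 1307 lower of 6752 tested, of which 789 and 871 were not clustering features. Apart from GstD1, Ilp7 and the 3 Hox genes, the genes valued in the preceding motor neuron account had adjusted p of 0.000472 (NetB) or less and the same direction in 5 of 5 libraries. Adjusted over the list alone, the counts differed for lineage transcription factors (7 higher, 35 lower), axon guidance (5 higher, 33 lower), transmitter receptors (13 lower), axonal transport (9 higher), monoamine receptors (11 lower), stress (7 higher, 3 lower), oxidative phosphorylation (5 higher), neuropeptide receptors (5 higher), synaptic genes (12 lower), channels (4 higher) and ribosomal proteins (0 higher, 1 lower). The median UMI count per cell was 12542.5 to 32775.5 in motor neurons of the 5 controls against 7600.5 to 10801 in other mature neurons. In the 2 controls with the longer barcode list the counts were 689 and 715, and without the library as a block 463 and 417.

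**Figure D2:**
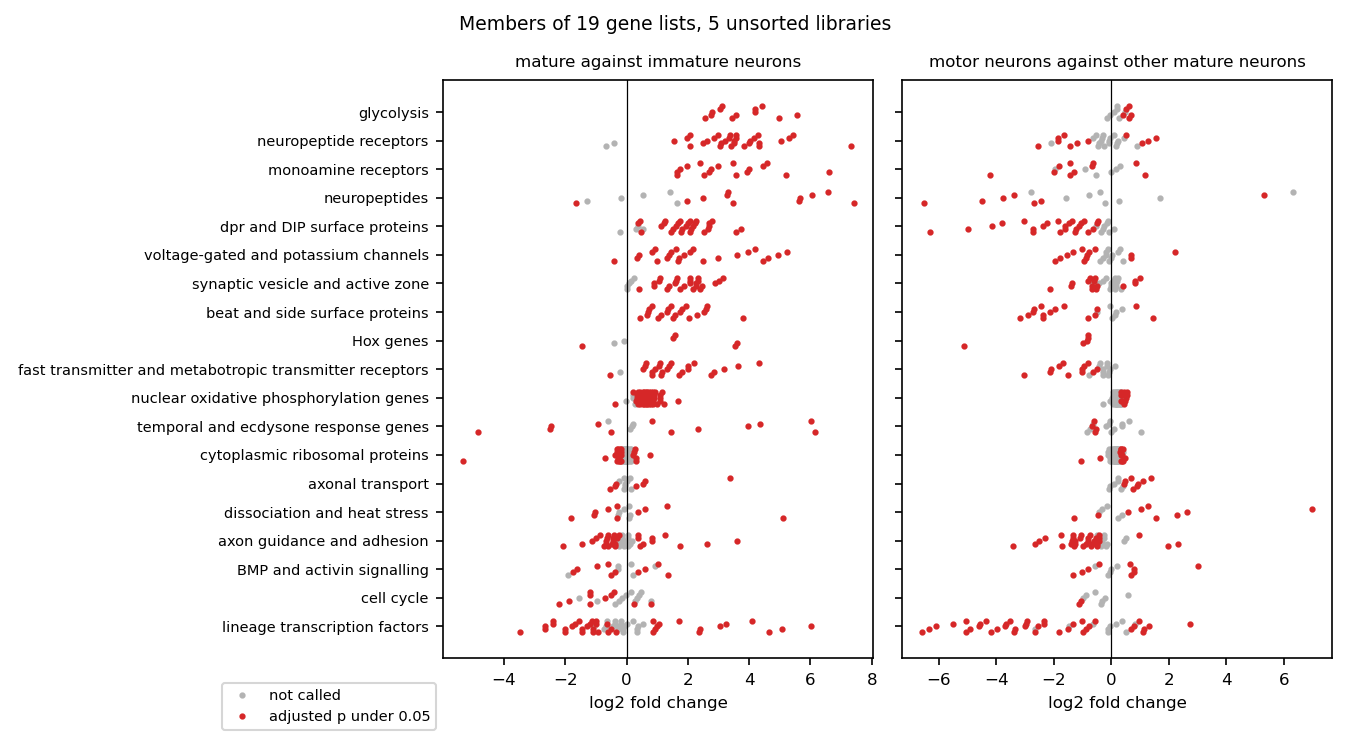
Log2 fold change (horizontal axis) of each tested member of the 19 gene lists, for mature against immature neurons (left) and motor neurons against other mature neurons (right), with 1 point per gene, red where the adjusted p is under 0.05. All 12 glycolysis genes lie to the right of 0 on the left panel, and none of the 32 dpr and DIP genes is called higher on the right panel.

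The transmitter comparisons asked how cholinergic, GABAergic and glutamatergic mature neurons differ, each against the mean of the other pair. Cholinergic neurons had acj6 at 125 ± 50.1 CPM against 1.39 ± 1.61 in GABAergic and 0.760 ± 0.520 in glutamatergic neurons (mean ± SD, n = 5, 5 and 4), and the neuropeptide gene spab at 638 ± 213 against 17.6 ± 3.55 and 24.5 ± 11.7. GABAergic neurons had DIP-lambda at 174 ± 30.8 CPM against 0.554 ± 0.635 in cholinergic and 0.436 ± 0.872 in glutamatergic neurons, and the transcription factor gene Fer3 at 79.6 ± 8.81 against 0.243 ± 0.337 and 1.12 ± 1.64. Glutamatergic neurons had ey, the fly Pax6 gene, at 48.8 ± 4.74 CPM against 1.28 ± 2.58 in cholinergic and 5.24 ± 5.10 in GABAergic neurons. The gene ey lies at 697689 to 721173 of chromosome 4, and spab at 2R 8963164 to 8968184.

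For cholinergic neurons, 17 of 52 lineage transcription factors were higher and 10 lower, with C15 (5.77 ± 0.42) and kn (4.64 ± 0.30) up (camera adjusted p = 6.27e-06). The factor otp stood at 56.6 ± 17.4 CPM, HLH4C at 46.3 ± 28.6 and TfAP-2 at 23.2 ± 6.41, with 0 UMIs of each in the glutamatergic neurons of the 4 controls used. Against a floor of 3 counts over the 3773076 UMIs of those cells (0.795 CPM), otp was at least 74.5-fold, HLH4C at least 64.4-fold and TfAP-2 at least 26.4-fold higher in cholinergic neurons. Neuropeptide genes had 6 higher, with spab (5.10 ± 0.10), and 1 lower, Nplp1, at 19.5 ± 1.99 against 429 ± 123 and 306 ± 156 CPM (adjusted p = 2.35e-10). The calls of both lists held with an estimated correlation, with adjusted p = 0.00662 for neuropeptides and adjusted p = 0.00829 for lineage factors. Both ended with no filter on low counts (camera adjusted p = 0.0683 and 0.0965). The dpr and DIP genes had 10 higher, such as DIP-eta (2.71 ± 0.32), and 1 lower (adjusted p = 0.000616, and adjusted p = 0.292 with an estimated correlation). The beat and side genes had 9 higher, such as beat-IIIc (1.57 ± 0.10), and 2 lower (adjusted p = 0.0348, and adjusted p = 0.288 with an estimated correlation). That call ended without control 2 (camera adjusted p = 0.0844), without control 3 (0.0621), with no filter (0.215), at 1000 UMIs or more (0.123) and with the gate of 1 UMI (0.0509). Oxidative phosphorylation genes had 9 lower and 51 not called (adjusted p = 6.12e-06, and adjusted p = 0.398 with an estimated correlation).

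For GABAergic neurons, 12 lineage transcription factors were higher and 8 lower, with Dbx (6.65 ± 0.29), inv (5.84 ± 0.28) and Lmx1a (3.62 ± 0.20) up and unc-4 (-4.97 ± 0.54, not called with the longer barcode list alone) down (camera adjusted p = 0.000270), and the call held with an estimated correlation (adjusted p = 0.0254). It ended with no filter on low counts (camera adjusted p = 0.978, the direction turned) and with the shorter barcode list alone (0.173). The segment polarity gene en stood at 59.1 ± 15.4 CPM in GABAergic and 1.58 ± 1.53 in cholinergic neurons, and was at least 66.8-fold higher than in glutamatergic neurons, which held 0 UMIs of it in the 4 controls used. It lies at 2R 11524006 to 11528210. Oxidative phosphorylation genes had 17 higher and 43 not called, by small amounts such as ATPsynF (0.31) (adjusted p = 2.02e-12, and adjusted p = 0.259 with an estimated correlation). The dpr and DIP genes had 6 higher and 3 lower (adjusted p = 0.00251, and adjusted p = 0.113 with an estimated correlation). That call ended without control 2 (camera adjusted p = 0.167), with either barcode list alone (0.459 for the longer, 0.0537 for the shorter), with no filter (0.190), with no replicate block (0.0648), with doublets kept (0.135) and with the gate of 1 UMI (0.0726). The beat and side genes had 6 higher and 1 lower (adjusted p = 0.00867, and adjusted p = 0.113 with an estimated correlation), which ended with no replicate block (camera adjusted p = 0.410). The stress list had 1 lower and 15 not called (adjusted p = 0.0189 downward, and adjusted p = 0.356 with an estimated correlation). That call ended without control 1 (camera adjusted p = 0.112), with the longer barcode list alone (0.178), with no replicate block (0.238) and with doublets kept (0.135).

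For glutamatergic neurons, 2 lists of surface protein genes were shifted lower, though not every member was. The beat and side genes had 8 lower, such as beat-Ia (-1.88), and 2 higher (camera adjusted p = 3.74e-07), and the dpr and DIP genes 11 lower, such as DIP-alpha (-2.67), and none higher (adjusted p = 1.54e-06). Neuropeptide genes had 2 lower and 1 higher (adjusted p = 0.00166). These 3 calls held with an estimated correlation (adjusted p = 0.0149, 0.0299 and 0.0374 in that order). The neuropeptide call ended with no filter on low counts (camera adjusted p = 0.226) and with the longer barcode list alone (0.135). Channel genes had 5 lower, such as Ih (-0.37, not called with the shorter barcode list alone), 1 higher and 18 not called (adjusted p = 0.00361, and adjusted p = 0.230 with an estimated correlation), a call that ended with no replicate block (camera adjusted p = 0.791, the direction turned) and with the shorter barcode list alone (0.0930). Of the lineage transcription factors 10 were higher, with ey (5.18 ± 0.37), unpg (4.06) and tj (3.14 ± 0.15), 13 lower and 29 not called, and camera did not call this list (adjusted p = 0.584).

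The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment tested 6929 genes and called 315 higher and 265 lower in cholinergic, 209 and 124 in GABAergic, and 203 and 227 in glutamatergic neurons. The genes named in the transmitter account had the same direction in every library compared. Adjusted over the list alone, cholinergic counts were 18 higher and 12 lower for lineage factors, 7 and 1 for neuropeptides, 13 and 1 for dpr and DIP, 9 and 4 for beat and side, and 0 and 16 for oxidative phosphorylation. The GABAergic counts were 13 and 12 for lineage factors, 40 and 0 for oxidative phosphorylation, 10 and 6 for dpr and DIP, 10 and 3 for beat and side, and 0 and 5 for stress. The glutamatergic counts were 2 and 12 for beat and side, 3 and 16 for dpr and DIP, 3 and 6 for neuropeptides, 1 and 9 for channels, and 12 and 18 for lineage factors. Control 3 gave 4 glutamatergic cells and was left out of that class. Counts fell to 39 and 35, 32 and 15, and 25 and 18 without the library as a block, and leaving out control 5 gave 157 lower cholinergic, 135 higher and 70 lower GABAergic, and 121 higher and 149 lower glutamatergic genes. Leaving out control 1 gave 130 higher GABAergic genes, and leaving out control 4 gave 137 higher GABAergic and 117 higher glutamatergic genes.

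The sorted libraries show which cells and genes GFP sorting enriched with each driver. Motor neurons made up 31.3% of the twit-Gal4 sorted cells (790 of 2522, exact 95% interval 29.5% to 33.2%) against 1.51% of control 2, and 49.1% of the Proc-Gal4 sorted cells (2215 of 4508, 47.7% to 50.6%) against 2.58% of control 5. Neurosecretory neurons were enriched as well, to 32.0% (30.2% to 33.9%) in the twit-Gal4 sort (20.4% at 1000 UMIs or more) against 1.24% in control 2, and to 7.96% (7.19% to 8.79%) in the Proc-Gal4 sort against 1.40% in control 5. Glia fell from 3.77% to 1.63% and from 6.58% to 9 of 4508 cells, and neuroblasts and ganglion mother cells from 5.83% to 0.634% and from 7.32% to 0.732%. Unnamed cells made up 24.4% of the twit-Gal4 sort. The neurosecretory share of control 2 rests on 38 cells. A neurosecretory cluster of 53 cells was led by CG12239 and lncRNA:CR44832, whose ratios were among the lowest in the twit-Gal4 sort. The rise of this class may thus not hold for every type in it.

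Each driver's own gene was higher in both sorts. The gene twit (2L 20852578 to 20857113) stood at 571 CPM over all cells of the twit-Gal4 sort against 48.0 in control 2, a ratio of 11.9 (95% interval 11.3 to 12.5), and at 925 against 102 CPM in the Proc-Gal4 sort, a ratio of 9.04 (8.76 to 9.33). Proc, the gene of the neuropeptide proctolin (2L 7864642 to 7871432), had ratios of 8.59 (8.43 to 8.76) in the twit-Gal4 sort and 7.65 (7.54 to 7.75) in the Proc-Gal4 sort, where it stood at 4161 against 544 CPM. The glutamate transporter gene VGlut (2L 2400295 to 2410662) had ratios of 2.16 and 2.64, the motor neuron factor eve (2R 9979319 to 9980795) 3.66 and 4.33, and Dad (3R 17054007 to 17070408), a BMP target, 3.95 and 2.26. The reporter sequence had ratios of 6.84 (599 against 87.6 CPM) and 15.9 (71.7 against 4.52 CPM). As a mean of per-cell CPM, the ratio of twit was 28.5 in the twit-Gal4 sort and 15.7 in the Proc-Gal4 sort, that of Proc in the Proc-Gal4 sort 12.1, and those of the reporter 17.5 and 28.2. At least 1 UMI of twit was found in 65.5% of twit-Gal4 sorted cells (35.6% after thinning to 1000 UMIs) against 3.37% (1.08%) of control 2, with 7.32% of the 41 glia of the sort as a background. The median depth, counted over the genes shared by all libraries, was 4668.5 UMIs over all cells of this sort, 5125 in its glia and 10077.5 in control 2. At least 1 UMI of Proc was found in 86.0% (70.5%) of Proc-Gal4 sorted cells against 16.9% (7.81%) of control 5, with 22.2% of the 9 glia of the sort (2 cells, 95% interval 2.81% to 60.01%) as a background that is too small to be precise. The glia of control 5 had 2.67%. The median depth was 6285 UMIs over all cells of this sort, 3519 in its glia, 9515 in control 5 and 11567 in its glia.

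**Figure D3:**
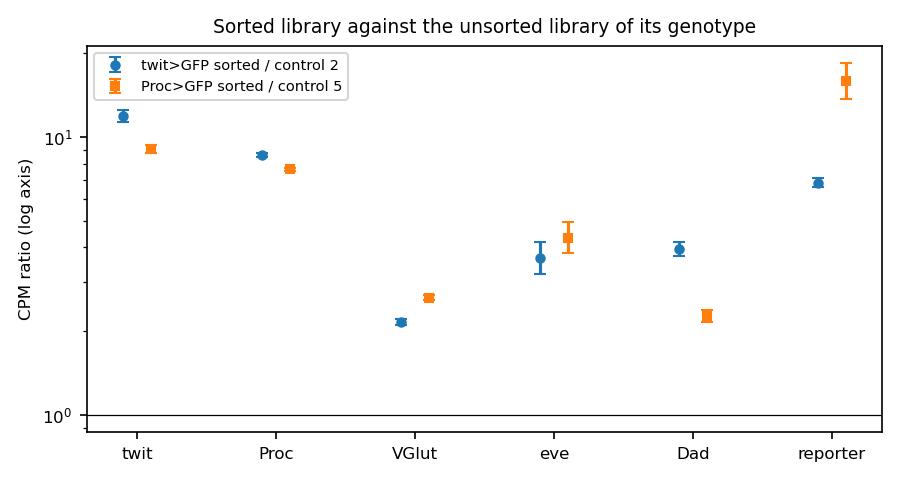
Ratio of CPM over all cells of a sorted library to CPM in the unsorted library of the same genotype (vertical log axis) for 5 genes and the reporter sequence, with 95% counting intervals and 1 library per point. All 12 ratios lie above 1, from 2.16 for VGlut to 15.9 for the reporter.

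Among the genes with the largest ratios were several neuropeptide genes. In the twit-Gal4 sort Hug stood at 614 CPM, with 0 UMIs in control 2, and was at least 8407-fold higher against a floor of 3 counts over control 2. The highest control held 257 CPM of Hug. FMRFa stood at 709 against 4.26 CPM, a ratio of 166 (143 to 194), and Dsk was at least 134-fold higher. Genes outside this group had ratios in the same range, such as CG6220 at 242.3 (182.9 to 328) and Cpr92A at 142.8 (54.95 to 528.7). In the Proc-Gal4 sort FMRFa stood at 2533 against 0.867 CPM, a ratio of 2921 (2128 to 4128), or 951.5 as a mean of per-cell CPM. Obp69a, named for an odorant-binding protein, had a ratio of 278.6 (76.63 to 2308). Orcokinin reached 18230 against 603 CPM, a ratio of 30.2 (29.8 to 30.6). As a mean of per-cell CPM it stood at 8607 in this sort, a ratio of 41.97. Ilp7 stood at 597 against 21.6 CPM, a ratio of 27.7 (25.9 to 29.6). The lowest ratios were 0.01715 for lncRNA:CR44832, 0.02037 for CG13203, 0.02115 for CG12239, 0.0273 for HLH4C, 0.0326 for Fer2 and 0.0336 for gsb-n in the twit-Gal4 sort. This order depends on the setting. At 1000 UMIs or more, lncRNA:CR44832 stood at 0.09253, CG12239 at 0.2296, Fer2 at 0.0681 and gsb-n at 0.0543, and with doublets kept lncRNA:CR44832 stood at 0.09862 and CG12239 at 0.1947. As a mean of per-cell CPM, lncRNA:CR44832 stood at 0.03624, CG12239 at 0.04461 and CG13203 at 0.03444. In the Proc-Gal4 sort e had a ratio of 0.00127 from 1 UMI (3.21e-05 to 0.0071), or 0.00232 at 1000 UMIs or more, and Def 0.00248 from 1 UMI, or 0.004005 as a mean of per-cell CPM. The astrocyte gene alrm had a ratio of 0.00128 (0.000468 to 0.00278), or 0.00251 as a mean of per-cell CPM, 0.00229 with doublets kept and 0.00193 at 1000 UMIs or more, and MFS9 0.00559. Hug lies at 3R 12526188 to 12529076 and FMRFa at 2R 9906294 to 9910457. In all, 297 genes were at least 2-fold over the highest control and 1598 under 0.5 of the lowest control in the twit-Gal4 sort, and 349 and 1552 in the Proc-Gal4 sort. With 1 library per sort these differences have no replicate check, and the intervals cover counting error only.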

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

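The tests of control 3, of the glycolysis genes and of the heat shock genes, and the use of splits that keep the pairing to judge chance, were chosen after the result was seen; the test of severed axons and the splits across libraries were set beforehand.

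Control 3 lay far from the other 4 controls in 2 of 19 values compared across the 5 controls, where about 1 in 20 passes by chance: hemocytes made up 1.351% of its cells against 0% in the others, where any share above 0 passes, and unnamed clusters 63.44% against 24.61% to 29.73%. At 1000 UMIs or more 2 of 21 values passed, hemocytes of control 3 (0.3694%) and glia of control 5 (12.41% against 7.671% to 8.975%), while the unnamed share of control 3 (34.76% against 26.63% to 32.31%) did not. Its shares of mature neurons (3.04%) and immature neurons (1.52%) were low too, short of the limit, and cells added from clusters led by nw and ImpE2, 21.4% of control 3, cannot be the whole reason, since without them the immature share was 1.934%, far under the lowest other control (23.6%). At 1000 UMIs or more the immature share of control 3 was 29.19%, beside 30.35% to 35.05%, and within that clustering its cells over the library's own minimum were 4.566% immature against 21.99% to 36.21%, which is consistent with the minimum leaving out smaller cells. The same large cells were 10.1% mature against 18.94% to 26.16% and 49.57% unnamed against 28.21% to 32.29%. At the UMI minimum of each library, an unnamed cluster of 259 cells came from control 3 alone. Its leading genes included the neuropeptide genes Trissin, AstA, spab and CCHa1. Another unnamed cluster of control 3 alone, of 99 cells, had FMRFa among its leading genes. Some neurons of control 3 thus appear to have clustered apart and stayed unnamed. How much of the low shares this explains remains open, as does a biological difference of this line, which alone has its genotype.

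Glycolysis genes were higher in mature than in immature neurons, with a median log2 fold change of 3.51. RNA of glia, which hold glycolytic transcripts, is argued against by the glial markers of the same sums: the median of the 4 tested was -0.1609 (-0.79 to 0.34), far below the lowest glycolysis gene (2.55). Selection of large cells by the UMI minimum is argued against by the median of 3.853 at 1000 UMIs or more. Both tests were chosen after the result was seen, so they argue against these technical explanations without excluding them. A change of sugar metabolism as neurons mature may be a candidate explanation, but it is a hypothesis found and tested on the same data. Only transcript levels were measured, which cannot decide it. The genotypes and the dissociation are shared by both classes and give no further test.

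The stress genes kay, Jra and puc were higher in motor neurons than in other mature neurons. Such levels of Jra and puc were not particular to motor neurons. In raw class sums, surface glia held Jra at 378 ± 143 and puc at 279 ± 162 CPM, beside 220 ± 93.7 and 273 ± 142 in motor neurons. The mean of kay was lower in surface glia, at 309 ± 172 beside 471 ± 258 CPM. A general stress of dissociation would move the heat shock genes, whose median was 0.123 (SD 0.856, 8 tested); members went both ways, with Hsp23 at 1.27 and Hsp70Bc at -1.29, so this stays open. Axons severed when the cord was taken out could be another reason, and part of the neurosecretory axons also leave the cord. In the neurosecretory class the median log2 ratio of the 3 genes to mature neurons was 0.09, 0.91, -0.12, 0.21 and 0.76 in controls 1 to 5, with a median of 0.2107. The bound set beforehand (under 0.5 in at least 3 of the 5 controls) was met, but by less than the spread between controls and in a class whose share of leaving axons is not known here, so severed axons and a trait of motor neurons cannot be told apart.

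Splits of the class sums that exchange classes within every library, as the pairing asks, gave as many called genes in 1 of 16 for mature against immature neurons (4766 genes, 608 as the highest other) and in 1 of 16 for motor neurons (2441 genes, 1 as the highest other), and 16 splits are too few for a share under 0.05. For the transmitter classes, 60 such splits were drawn, the real one included. As many genes were called in 1 of them for cholinergic neurons (580 genes, 340 as the highest other), a share under 0.05. For glutamatergic neurons it was 2 (430 genes, 518 as the highest other), so a drawn split called more than the real one. For GABAergic neurons it was 3 of 60 (333 genes, 418 as the highest other), which does not exclude chance. Only 2 glutamatergic draws kept 1 class in 4 libraries, and 1 of these called as many genes. Of 10 such GABAergic draws, 2 were as large. The shares thus depend on which of the 2592 possible splits were drawn, and chance is not excluded for glutamatergic neurons either. The splits as large kept 1 class together in 4 libraries, which points to the real classes as a structure of the samples, while splits that kept 1 class in 3 or fewer libraries called at most 1 gene. Splits that ignore the pairing gave as many genes in 1 of 30 for each comparison, with 608, 0, 1, 6 and 1 as the highest other, and are not used to exclude chance. An earlier run with 40 within-library draws gave 1 for each transmitter class and is not used, since the larger run gave the less favourable counts.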

How the results depend on the processing

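All alternatives were planned before the data were examined, so no test here was chosen after the result was seen. With DESeq2 in place of edgeR every count of called genes stayed within 1.5 times, and the median fold change moved by at most 0.0646 (log2). Except where given here, the causes were not tested.

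Without the replicate block that follows the pairing by library, the genes higher and lower were 1152 and 1050 for mature against immature neurons, 463 and 417 for motor neurons, 39 and 35 for cholinergic, 32 and 15 for GABAergic and 25 and 18 for glutamatergic neurons. With the longer barcode list only, motor neurons had 689 and 715, GABAergic neurons 130 higher and glutamatergic neurons 120 and 145. With the shorter list only, cholinergic neurons had 139 and 108, GABAergic 84 and 52 and glutamatergic 81 and 86, with fewer libraries in each case. With no filter on low counts there were 536 higher cholinergic, 369 higher and 225 lower GABAergic and 433 lower glutamatergic genes, and at 1000 UMIs or more 210 lower GABAergic genes. Leaving out each control gave ranges of 157 to 315 lower cholinergic genes, 130 to 251 higher and 70 to 157 lower GABAergic genes, and 117 to 244 higher and 149 to 280 lower glutamatergic genes.

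Camera with an estimated correlation called 0 lists for mature against immature neurons (10 with the preset one), 0 for motor neurons (11), 2 for cholinergic (5), 1 for GABAergic (5) and 3 for glutamatergic neurons (4). For GABAergic neurons, 3 lists were called with no filter, 2 with no replicate block, 3 with the longer barcode list and 3 with doublets kept. For cholinergic neurons, 4 lists were called with no filter, of which 2 were among the 5 called otherwise.

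At 1000 UMIs or more, neurosecretory neurons made up 0.854% and glia 9.25% of cells. Thinned to 1000 UMIs, 8.92% of mature neurons were cholinergic and 19.1% GABAergic, since fewer cells reach the gate. In the twit-Gal4 sort, motor neurons made up 34.3% with classes from all 5 controls, 27.0% with doublets kept and 25.1% at 1000 UMIs or more, and neurosecretory neurons 43.7%, 29.5% and 20.4%. In the Proc-Gal4 sort, motor neurons made up 56.1%, 47.2% and 45.6%, and neurosecretory neurons 9.14% with classes from all controls and 7.05% at 1000 UMIs or more. The ratio of twit in the twit-Gal4 sort was 28.5 as a mean of per-cell CPM. The ratio of Proc in the Proc-Gal4 sort was 12.1 as such a mean, 8.30 at 1000 UMIs or more and 7.76 with doublets kept.

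Of the named genes, 1 turned direction: mamo in motor neurons (-0.56) stood at 0.14 at 1000 UMIs or more, where it was not called. Without the replicate block, 74 of 85 named genes kept their call for mature against immature neurons, 48 of 79 for motor neurons, and 21 of 65, 18 of 52 and 17 of 51 for the cholinergic, GABAergic and glutamatergic classes. Depth limits what a count of 0 can show: over the 3773076 UMIs of the glutamatergic class in 4 controls, 3 counts are 0.795 CPM.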

Other observations

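No test here was chosen after the result was seen, and the values have no test of their own; the genes were picked after their values were seen.

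Syp, which codes for an RNA-binding protein of late neuroblasts, stood at 8579 ± 2741 CPM (mean ± SD, n = 5, raw class sums) in neuroblasts and ganglion mother cells, 1306 ± 326 in immature and 274 ± 126 in mature neurons. Imp, its counterpart of early neuroblasts, stood at 101 ± 56.1, 275 ± 97.8 and 1486 ± 733 CPM, with overlapping ranges in progenitors and immature neurons. Eip93F stood at 436 ± 345 CPM in progenitors, 360 ± 229 in immature and 16.4 ± 10.5 in mature neurons, again with overlapping ranges in the first pair. Hr38 stood at 342 ± 101 CPM in mature, 362 ± 124 in monoaminergic, 202 ± 59.7 in motor and 4.60 ± 2.62 in immature neurons.

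At 1000 UMIs or more, 3 clusters with the cell death genes skl, grim and rpr among their leading genes were found in all 5 controls. The cluster of 273 cells made up 0.868% ± 0.196 of cells and was named immature. It held Ubx at 1141 ± 441 CPM against 243 ± 102 in all other cells, abd-A at 594 ± 278 against 144 ± 75.4 and Abd-B at 320 ± 122 against 127 ± 42.3. Another, of 170 cells (0.628% ± 0.288), was named as progenitors and held Antp at 976 ± 244 against 452 ± 109 CPM and nerfin-1 at 508 ± 227 against 92.5 ± 18.2, and Ubx at 128 ± 64.4 against 246 ± 103 CPM (higher in the cluster in control 1), abd-A at 18.3 ± 19.5 against 146 ± 76.1 and Abd-B at 25.1 ± 21.6 against 128 ± 41.9. An unnamed cluster of 251 cells, with the same 3 genes among its leading ones, went no single way between controls for Ubx. It held Ubx at 162 ± 174 against 246 ± 103 CPM, with 441.3 against 322.1 in control 2, which gave more of the cells than any other control. It held abd-A at 95.9 ± 79.1 against 146 ± 76.2 and Abd-B at 58.3 ± 39.8 against 128 ± 41.9. Both were lower in the cluster in controls 1, 2, 4 and 5. Control 3 gave 10 cells of this cluster, with 3 UMIs of abd-A (230.5 against 43.47 CPM) and 1 UMI of Abd-B (76.85 against 72.77). These counts are too few to give a direction. In surface glia, cortex glia and astrocytes, kay stood at 309 ± 172, 187 ± 79.8 and 190 ± 88.8 CPM, Jra at 378 ± 143, 252 ± 132 and 236 ± 101, and puc at 279 ± 162, 371 ± 238 and 256 ± 156, beside 471 ± 258, 220 ± 93.7 and 273 ± 142 in motor neurons. Orcokinin stood at 38720 ± 47190 CPM in neurosecretory neurons, from 5666 to 121500 between controls.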
